A study of Mus musculus with 2 samples.

How the data were processed

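RNA was measured by sequencing of polyadenylated RNA from whole mouse uterus on gestational day 8, with 1 library of METTL3-overexpressing uterus and 1 of control uterus. The grouping came from the genotype given in the labels: Rosa26lslMettl3/+;PgrCre/+ for METTL3-OE and Rosa26lslMettl3/+ without Cre for the control. The labels do not say how many animals went into each library. Libraries were prepared with a TruSeq RNA kit, per the labels' protocols.

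HISAT2 2.2.1 and Cufflinks 2.2.1 are named in the submitters' processing notes, as are the builds mm9 and mm10, without the build used for each step. The deposited tables hold 1 value per gene, which was read as FPKM (fragments per kilobase of transcript, scaled to the number of mapped fragments). The headers give no unit. FPKM was inferred because Cufflinks reports it and because the lowest values scale with transcript length and depth. The authors' scaling between libraries, their filters and their handling of reads that map to several places are not given in the sources used here. Each table lists the same 20634 genes, each with a symbol and an Ensembl identifier. Of these, 20557 identifiers matched the GENCODE M21 annotation of GRCm38 (mm10), and 20432 were protein-coding there. Coordinates are from that annotation, since the tables give none. No mitochondrially encoded gene is listed, so that list could not be evaluated. A value of 0 was listed for 4399 genes in both libraries.

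Depth was estimated from the values. In genes with a single annotated transcript of at least 1500 bases, the value multiplied by the transcript length, less a fragment-length correction of 340 bases in METTL3-OE and 300 bases in the control, came in steps. The best-fitting step was 0.043 in the METTL3-OE library and 0.0552 in the control library. The lowest steps fell within 0.1 of a whole number of fragments in 64.9% of 208 values and 72.9% of 225 values respectively. A step fixed beforehand would give 20% by chance. Step and correction were fitted to these same values, so the share expected by chance is above that. These steps correspond to about 23300000 and 18100000 fragments, a depth ratio of 1.28. For a transcript of 2 kb, FPKM 5 then rests on about 233 and 181 fragments. The 95% counting interval of a log2 ratio is then about ± 0.28 at FPKM 5, ± 0.63 at FPKM 1 and ± 0.06 at FPKM 100. The intervals given for the folds of single genes are exact Clopper-Pearson intervals on the approximate fragment numbers, taken over the longest annotated transcript. All these intervals cover counting error only, since fragments amplified by PCR are not independent molecules.

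With 1 library per genotype no test between genotypes was possible, and no p-value is given. Log2 ratios are METTL3-OE over control of FPKM plus a pseudocount of 1, which understates the difference of low genes. Plain folds are ratios of the deposited FPKM. A gene was measured when it had FPKM of at least 1 in at least 1 library. Genes at least 2-fold apart on the log2 scale with pseudocount were counted per direction. The gene lists, the rule for naming genes and all alternatives but 2 were fixed before the data were examined. There were 29 gene lists, of which 12 held markers of cell types or other tissues. For each list with at least 4 measured members, the median log2 ratio was placed among the medians of 10000 random lists of the same size. The random lists were drawn from measured genes outside the list and matched on mean log expression in 20 bins. A list was said to stand apart below percentile 2.5 or above percentile 97.5. These percentiles describe the 2 libraries and are not p-values, because genes are not independent replicates.

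The rule for naming takes Mettl3 and Pgr, then the 12 highest and the 12 lowest log2 ratios among genes with FPKM of at least 5 in at least 1 library, leaving out predicted genes, small RNAs, Rik clones and immunoglobulin or T-cell receptor segments. It also takes, for each list, the 2 to 4 members with the largest absolute log2 ratio and members that go against the median. Gt(ROSA)26Sor, also in the rule, was not analysed here.

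The alternatives tried were pseudocounts of 0.1 and 0.5, scaling by the median ratio or by a trimmed mean of log ratios, rescaling without the 10 most abundant genes of either library, other filters on low values, thresholds of 1.5-fold and 4-fold, the most abundant row per symbol, and random lists without matching. Removing genes with near-identical copies, and subtracting the median of genes in the same transcript length and GC bin, were added after seeing the data. Near-identical copies were sought with BLAST 2.17.0 by aligning the annotated transcripts of genes at least 2-fold apart and of list members to all annotated transcripts, at 95% identity or more over at least 50% of the transcript. The procedure was tested on simulated data with Poisson counts at the estimated depths for all 20634 genes. Of 50 genes with mean FPKM of at least 5 planted at 3-fold in each direction, 100% were recovered, and 0% of the 50 planted at 1.5-fold in each direction were counted. With 1000 random lists per test list, 6% of 100 unmoved lists of 15 genes stood apart, as did 100% of 100 lists shifted by 0.4 on the log2 scale and 100% of 100 lists shifted by -0.4. These simulations held independent genes and counting error only, so they check the calculation and not its error rate on real libraries. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1 was used.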

Results

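Gene expression was profiled in whole uterus of pregnant mice on gestational day 8, when the uterine stroma around the implanted embryo has turned into decidua. The METTL3-OE uterus carried a Cre-inducible Mettl3 transgene at the Rosa26 locus together with PgrCre, which expresses Cre recombinase from the progesterone receptor gene. The control uterus carried the transgene without Cre. METTL3 is the catalytic subunit of the complex that methylates adenosine in messenger RNA to m6A. The comparison addresses how uterine gene expression differs with conditional METTL3 overexpression on this day. Cre and its insertion at the progesterone receptor gene differ along with it, so their effects cannot be told apart. There was 1 library per genotype, of about 23300000 fragments for METTL3-OE and 18100000 for the control as estimated from the FPKM values, and 12302 genes reached FPKM 1 in at least 1 library. No difference below can be set against a spread between animals, and every comparison is between these 2 libraries. Folds are ratios of FPKM, while log2 ratios and 2-fold counts use FPKM plus 1, which draws low genes towards 0.

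Mettl3 was expressed at 91.1 FPKM in the METTL3-OE library and at 15.4 FPKM in the control library, a 5.91-fold difference (95% counting interval 5.39 to 6.49). With the pseudocount of 1 it had the second-highest log2 ratio of all genes eligible for naming, 2.49, which is the direction its label gives. With a pseudocount of 0.5 Rpl36-ps3 (2.58) passed Mettl3 (2.53). Fragments of the transgene and of the endogenous gene (ENSMUSG00000022160; mm10 chromosome 14, 52294841 to 52305128, minus strand) are summed in the Mettl3 value. Pgr, which encodes the progesterone receptor and carries the Cre insertion in METTL3-OE mice, stood at 31.4 and 30.9 FPKM, a 1.02-fold difference (95% counting interval 0.974 to 1.06; ENSMUSG00000031870, mm10 chromosome 9, 8899833 to 8968611, plus strand). None of the 9 measured members of a list of METTL3 partners and other RNA methyltransferases differed by 2-fold. The 6 measured members of the METTL3 complex were all slightly higher in METTL3-OE. Among them were Cbll1 (log2 ratio 0.30), Mettl14, the partner subunit of the METTL3 heterodimer (0.30), and Zc3h13 (0.28). The 3 lower members, Mettl16 (-0.13), Zcchc4 (-0.17) and Mettl5 (-0.18), are methyltransferases outside that complex, so the list mixes both groups. The list median of 0.23 lay at percentile 93.0 of matched random lists, and was 0.15 with trimmed-mean scaling and 0.07 at percentile 75.6 with transcript length and GC content taken out. The 12 measured m6A readers and erasers were all within 2-fold as well, with a median of 0.11 at percentile 78.3, which was 0.00093 after the same correction. Among them Igf2bp2, an m6A reader, was lowest at -0.44 and Hnrnpa2b1, which has a near-identical copy, highest at 0.23.

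Across the transcriptome the 2 libraries were close. Of 12302 measured genes, 133 were at least 2-fold higher in METTL3-OE, 126 were at least 2-fold lower, and 12043 (97.9%) lay within 2-fold. Ltf, the estrogen-responsive iron-binding protein lactotransferrin, had the highest log2 ratio of the genes eligible for naming, 2.57. It was at 5.74 FPKM in METTL3-OE and 0.135 FPKM in the control. The control value rests on about 6 fragments, so that the fold of 42.4 has a 95% counting interval of 19.3 to 116. Jchain, the joining chain of secreted IgA and IgM, was 3.88-fold higher (20.5 against 5.29 FPKM), and Pigr, the receptor that carries these antibodies across epithelium, 4.41-fold higher (10.1 against 2.30 FPKM). The water channel Aqp5 was 3.75-fold and the surfactant protein gene Sftpd 3.32-fold higher. The other genes named by rank were Slc18a3 (8.03-fold), Wfdc10 (4.66-fold), Fam13a (3.81-fold), Sumo2 (3.19-fold), Rps27rt (3.69-fold) and the pseudogene Rpl36-ps3 (10.7-fold). Rps27rt and Rpl36-ps3 have near-identical copies, so their values are uncertain.

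The 12 lowest log2 ratios among genes eligible for naming included 3 kallikrein-related peptidase genes of a cluster on chromosome 7. Klk7 was at 0.566 FPKM in METTL3-OE and 10.1 FPKM in the control (17.8-fold lower, 95% counting interval 11.3 to 29.6). Klk9 was 7.59-fold and Klk10 8.77-fold lower. The small proline-rich genes Sprr2d (5.96-fold) and Sprr2h (4.12-fold), which encode cornified-envelope proteins, were lower as well. Spink1, a secreted protease inhibitor of the uterine glands, was at 74.2 FPKM in METTL3-OE and 273 FPKM in the control (3.68-fold lower). The remaining genes named by rank were Orm1, an acute-phase plasma protein (8.04-fold lower), Ntn5 (6.19-fold), Necab2 (6.18-fold), Guca2a, a guanylate cyclase activator (5.69-fold), Gdpd2 (4.51-fold) and Acsbg1, an acyl-CoA synthetase (4.03-fold).

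**Figure D1:**
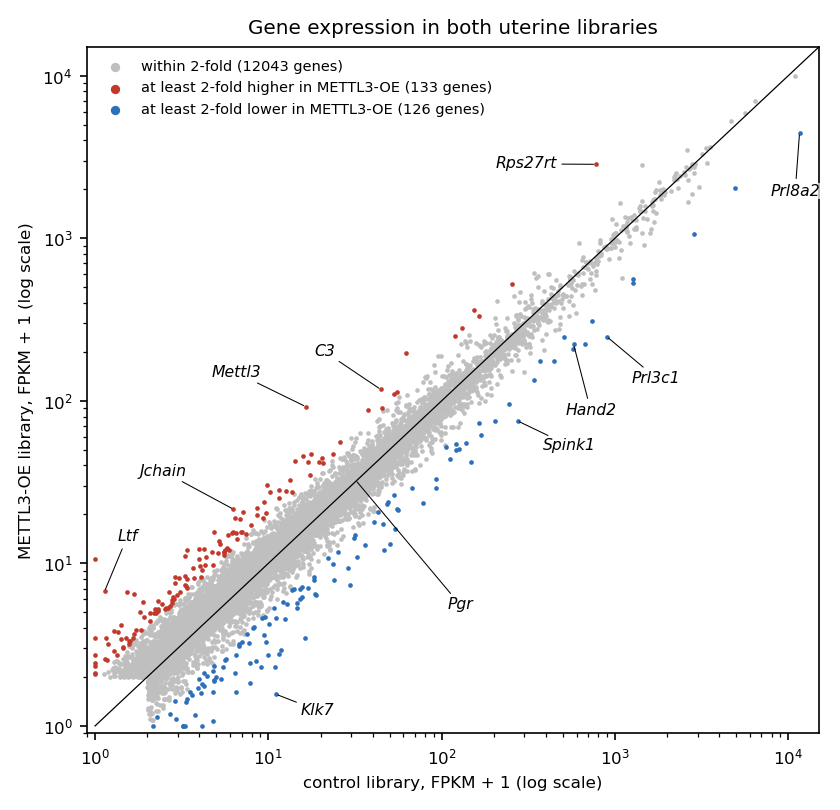
FPKM plus 1 of each of the 12302 measured genes in the control library (x axis, log scale) and the METTL3-OE library (y axis, log scale). The line marks equal values; 133 genes at least 2-fold higher in METTL3-OE are red, 126 at least 2-fold lower are blue, and Mettl3 and Ltf stand far above the line while Klk7, Prl3c1 and Prl8a2 stand below it.

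Of the 24 measured members of the decidualization list, 17 were lower and 7 higher in the METTL3-OE library. They had a median log2 ratio of -0.24, below all 10000 matched random lists, with 5 members at least 2-fold lower, 1 at least 2-fold higher and 18 within 2-fold. The decidual prolactin-family hormones led the difference. Prl8a2, the decidual prolactin-related protein and the most abundant transcript of the control library, was at 4435 against 11602 FPKM (2.62-fold lower). Prl3c1 was at 247 against 897 FPKM (3.63-fold lower). Hand2, a progesterone-dependent stromal transcription factor, was 2.60-fold lower (221 against 576 FPKM), and Cryab, a small heat shock protein, 2.40-fold lower (532 against 1274 FPKM). The fifth such member was Htra1, a secreted serine protease (2.27-fold lower). Members against the median were Dio2, a deiodinase (2.64-fold higher), and Foxo1, a transcription factor of stromal differentiation (12.6 against 7.15 FPKM, log2 ratio 0.74). Named after their values were seen, the decidual regulators Bmp2 (214 against 320 FPKM, log2 ratio -0.58) and Wnt4 (84.7 against 94.0 FPKM, -0.15) were within 2-fold, as were Hoxa10 (0.05) and the decidual enzyme gene Tdo2 (0.27). A second list of 8 measured decidual genes, drawn up later, had a median of -0.06, with 3 members above 0.2 (Igfbp3, Ptgis and Prl6a1) and 3 below -0.2 (Ctla2b, Dio3 and Bmp8a). Beside these genes, smooth muscle markers were higher (median log2 ratio 0.81) and trophoblast markers lower (-0.42) in the same METTL3-OE library.

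The progesterone receptor list did not stand apart. It does not cover all progesterone-dependent genes, since Hand2, for one, was placed in the decidualization list. The 14 measured members of the progesterone receptor list were all within 2-fold. They had a median log2 ratio of 0.0027 at percentile 24.8, with a negative sign under median-ratio (-0.07) and trimmed-mean (-0.08) scaling. With transcript length and GC content taken out, the median was -0.15 at percentile 2.17, past the lower limit. Il13ra2 (-0.69) and the receptor co-chaperone Fkbp5 (-0.39) were lower, and Fkbp4 (0.37), the other co-chaperone, was higher.

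Smooth muscle genes were mostly higher in METTL3-OE, with positive log2 ratios in 12 of 14. The 14 members, which mark the myometrium, had a median log2 ratio of 0.81, above all 10000 random lists, with 4 members at least 2-fold higher and none at least 2-fold lower. Smooth muscle actin Acta2 was at 525 against 252 FPKM (2.08-fold), smooth muscle myosin Myh11 at 112 against 53.9 FPKM (2.09-fold), Myl9 at 333 against 163 FPKM (2.04-fold) and myosin light chain kinase Mylk at 89.3 FPKM (2.03-fold). Des (-0.16), which decidual cells also express, and Myocd (-0.17) went the other way. Of 19 extracellular matrix genes 17 were higher and 2 lower, with a median of 0.61, also above all random lists, although only Lum, a collagen-binding proteoglycan, reached 2-fold (109 against 52.3 FPKM). Col6a2 (1.76-fold), Col5a1 (1.75-fold) and Col6a1 (1.72-fold) were next. Eln, encoding elastin, was lower (log2 ratio -0.65). Longer transcripts had higher ratios in general (Spearman's rho 0.22 across 12295 genes, which are not independent replicates), and with transcript length and GC content taken out the matrix median was 0.46, again above all random lists.

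Estrogen-response genes had the highest list median, 0.98 over 11 measured members, above all 10000 random lists. Of these, 5 were at least 2-fold higher, none was at least 2-fold lower and 6 were within 2-fold. Beside Ltf and Aqp5, the complement component gene C3 was at 117 against 43.4 FPKM (2.68-fold) and Lcn2, an iron-scavenging lipocalin, at 24.1 against 10.5 FPKM (2.29-fold). Sprr2f was at 2.77 against 0.354 FPKM (7.83-fold), a fold that is uncertain because the control value is below 1 FPKM. Sprr2d and Sprr2h, of the same family as Sprr2f but not on the list, went the other way (1.76 against 10.5 FPKM and 11.0 against 45.5 FPKM). The estrogen receptor gene Esr1 itself had a log2 ratio of 0.01, and Klf4 (-0.06) was the only lower member. Of 15 epithelial markers 12 were higher and 3 lower, all within 2-fold, with a median of 0.44, above all random lists. Tacstd2 (0.98), Krt7 (0.84) and Cldn7 (0.78) were the highest, while the tight-junction gene Cldn3 was lower (-0.77). Gland markers diverged. Spink1 was 3.68-fold lower, Fxyd4 was at 1.12 FPKM in METTL3-OE and listed at 0 in the control, and Prap1, a proline-rich secreted protein of pregnancy, was 1.97-fold higher (2817 against 1428 FPKM). The gland median of 0.11 over 7 members lay at percentile 88.6. Over the 6 members with an annotated length, which leaves out Kiss1, it was 0.45 before and 0.50 after length and GC content were taken out, the latter above all random lists. It also passed the upper limit with no filter (0.20 over 11 members) and without the most abundant genes (0.28 over 8 members).

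Of 13 retinoic acid genes 10 were higher and 3 lower, with a median of 0.49, above all random lists. Cyp26b1, which degrades retinoic acid, was 2.51-fold higher (6.01 against 2.39 FPKM), its relative Cyp26a1 2.04-fold (log2 ratio 0.93) and the synthesizing enzyme Aldh1a2 1.87-fold (105 against 56.1 FPKM). The retinoic acid-binding protein gene Crabp2 was 4.34-fold lower (0.885 against 3.84 FPKM). Smooth muscle (0.81), matrix (0.61) and epithelial (0.44) medians were higher in the same library.

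**Figure D2:**
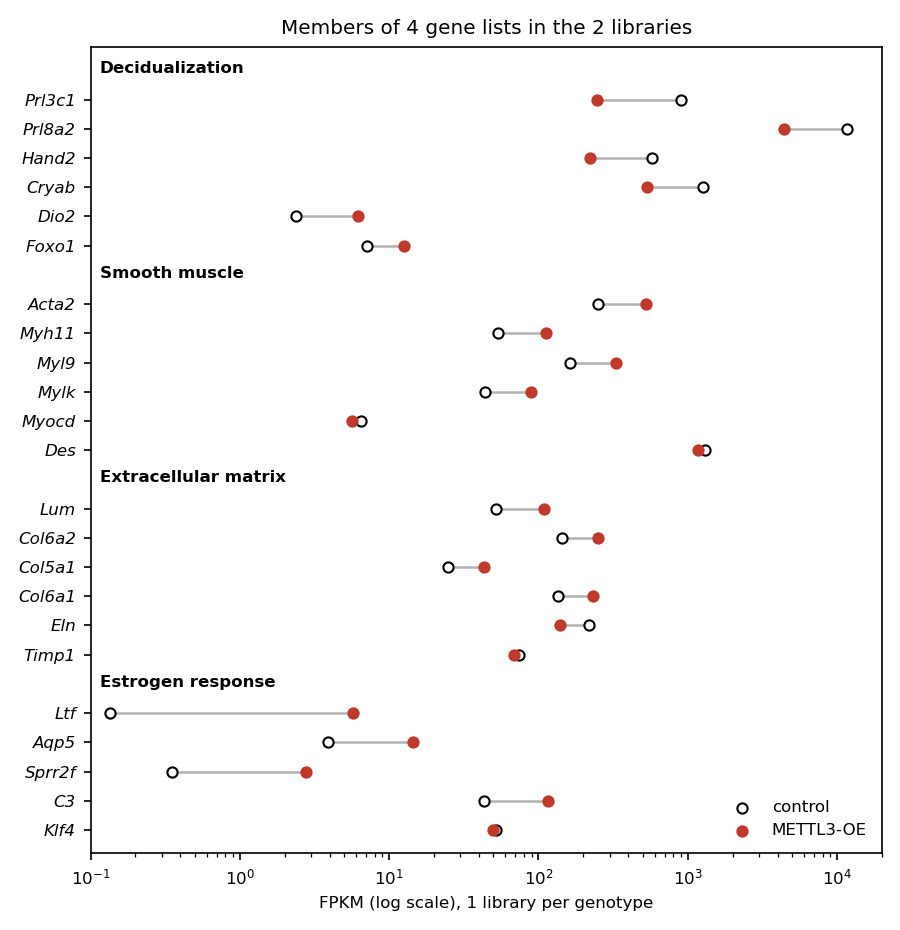
FPKM (x axis, log scale) in the control library (open circles) and the METTL3-OE library (filled red circles) of the members with the largest absolute log2 ratios, and up to 2 members going against the median, in 4 lists. Prl3c1, Prl8a2, Hand2 and Cryab were lower in METTL3-OE, and Acta2, Myh11, Lum, Ltf and C3 were higher.

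Leukocyte markers split by cell type. Of 16 natural killer genes 15 were lower and 1 higher, with a median of -0.26 at percentile 0.01. Gzma was 2.06-fold lower (51.0 against 105 FPKM), Gzmb 1.62-fold lower and Gzmg 1.37-fold lower, while the receptor gene Klrk1 was higher (log2 ratio 0.55). Of 13 macrophage genes 10 were higher and 3 lower, all within 2-fold, with a median of 0.39 at percentile 99.95. C1qa (0.73), Mrc1 (0.55) and C1qb (0.54) led this list, and Cd68 (-0.39), Csf1r (-0.26) and Fcgr1 (-0.21) went against it. Of the neutrophil markers only S100a8 (206 against 568 FPKM, 2.76-fold lower) and its partner S100a9 (16.5 against 15.8 FPKM) were measured. Of the T and B cell markers only Jchain, Cd3g (log2 ratio -0.75) and Lck (0.04) were measured, and neither list was ranked. Endothelial markers were within 2-fold (median -0.05 over 14 members, percentile 16.8), from Cldn5 at -0.65 to Tek at 0.30. Globin and other erythroid genes had a median of -0.24 over 5 members at percentile 5.06, inside the limits, but lay past the lower limit with no filter on low values (percentile 0.95 over 8 members) and with unmatched random lists (percentile 1.49). Hba-a2 was at -0.36 and Hba-a1 at -0.29, which are near-identical copies of each other.

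Markers of the conceptus were mostly lower in METTL3-OE. The labels do not say how many implantation sites went into each library or whether embryos were removed, so these values cannot be put per site. All 12 measured trophoblast markers had negative log2 ratios (median -0.42, percentile 0.01). Prl4a1 was at 3.22 against 9.03 FPKM (2.81-fold lower), Rhox9 2.62-fold lower and Hand1, a giant cell transcription factor, 1.60-fold lower. The most abundant was Prl3d1, a placental lactogen gene, at 52.3 against 63.8 FPKM, which shares near-identical sequence with Prl3d2 (10.1 against 13.7 FPKM) and Prl3d3, so the split between them is uncertain. Of the 6 measured embryo and yolk sac markers, 5 were lower (median -0.73, below all random lists). Apoa1 was at 2.18 against 5.03 FPKM, the transport protein gene Ttr at 0.808 against 2.33 FPKM and the pluripotency factor gene Pou5f1 at 1.26 against 2.86 FPKM, while Utf1 was higher (log2 ratio 0.63). With no filter on low values the embryo and yolk sac median was -0.12 over 18 members, at percentile 0.13. The decidualization median was lower and the muscle median higher in the same library. None of the 4 Y-linked genes reached 1 FPKM.

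Of 25 cell cycle genes 23 were higher and 2 lower, all within 2-fold, with a median of 0.26, above all random lists. Cenpe (0.53) and Top2a (0.44) were highest, and Rrm2, a ribonucleotide reductase subunit at 1258 against 1684 FPKM, was lower (-0.42). Of 14 cholesterol biosynthesis genes 12 were lower (median -0.22, percentile 0.02), as were 14 of 16 hypoxia and glycolysis genes (median -0.22, percentile 0.17), all within 2-fold. Ldlr (-0.72), Lss (-0.69) and Dhcr7 (-0.63) led the former, and Adm (-0.88) and Ndrg1 (-0.58) the latter, while the glucose transporter gene Slc2a1 was higher (0.54). Of 20 interferon-response genes 12 were lower and 8 higher, all within 2-fold (median -0.11, percentile 0.19), with Oasl1 at -0.53, Usp18 at -0.52 and Stat1, which has a near-identical copy, at 0.20. Inflammatory genes did not stand apart (median -0.04 over 9 members, percentile 11.5), with Cxcl5 at 2.81 against 0.284 FPKM and Cxcl10 at 1.64 against 3.87 FPKM. The p53 targets did not either (median 0.08 over 12 members, percentile 63.6), though Eda2r was 3.47-fold higher, and with length and GC content taken out their median was -0.0018. Medians of tissue markers differed in the same library as all these groups, from 0.81 for smooth muscle and 0.44 for epithelium to -0.26 for natural killer cells and -0.42 for trophoblast.

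Reference groups were near equality. The 12 housekeeping genes had a median of 0.024 at percentile 74.2, from Ubc at -0.26 to Polr2a at 0.14. The 33 ribosomal protein genes had a median of 0.035, from Rps27a at -0.24 to Rpl5 at 0.20. All of them but Rpl8, Rps3 and Rps5 have near-identical copies. So do Actb, Gapdh, Ppia, Rplp0 and Ywhaz among the housekeeping genes, and values of genes with copies are uncertain. The housekeeping and ribosomal medians were both negative under median-ratio scaling (-0.049 and -0.038) and trimmed-mean scaling (-0.057 and -0.047). The ribosomal median lay at percentile 99.35 of matched lists but at percentile 26.1 without matching on expression. Immediate early genes, which respond to tissue handling, had a median of -0.12 at percentile 1.35, with 7 of 12 members lower and 5 higher, among them Zfp36 at -0.52 and Egr1 at 0.26. This list lay at percentile 5.70 with transcript length and GC content taken out and at percentile 3.03 with a filter at FPKM 5, both inside the limits. Median-ratio and trimmed-mean scaling take 0.07 and 0.08 off the log2 ratio of abundant genes, which moves list medians near 0 by over 1.5 times, among them interferon response (-0.18 and -0.19). In all, 16 of 25 ranked lists stood apart, 8 in each direction, where about 1.25 would by chance if genes were independent. Genes of one list share cell types and regulation, and the random lists do not carry that.

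**Figure D3:**
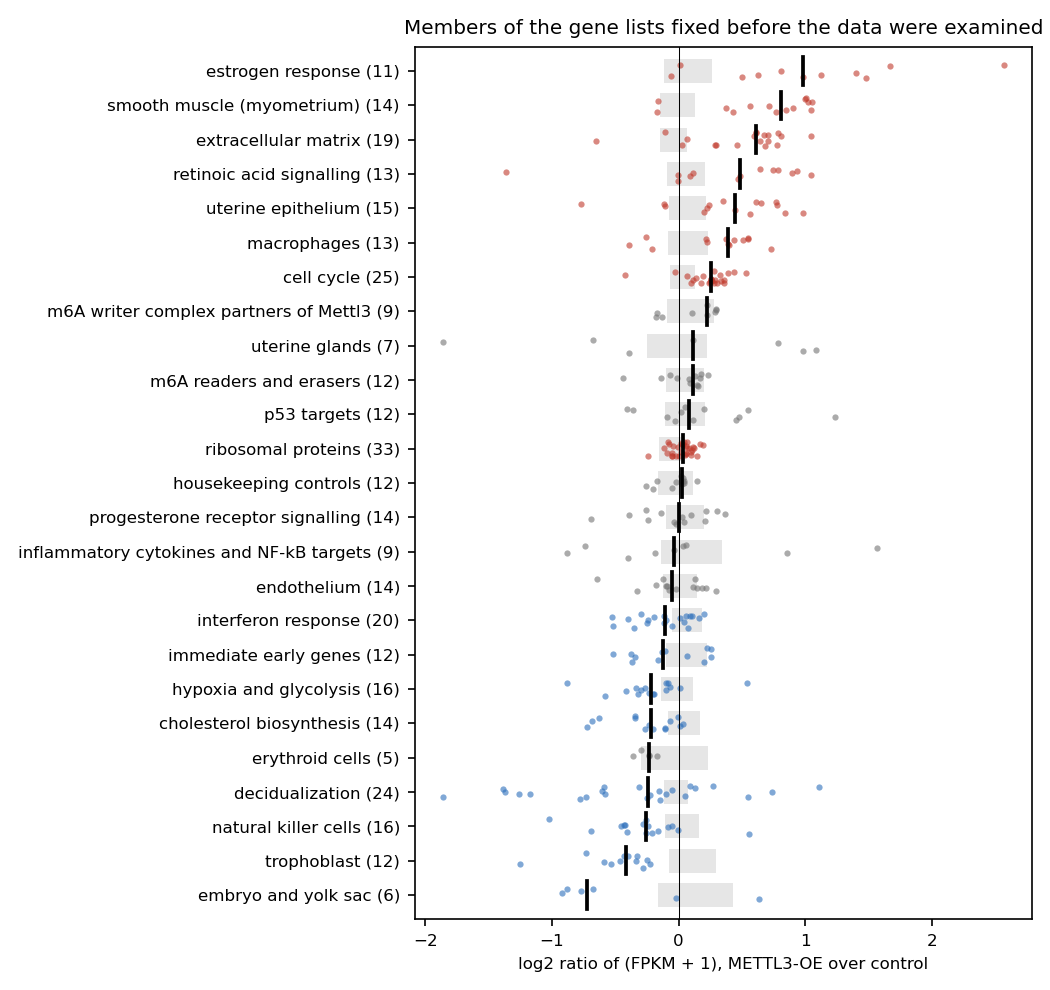
Log2 ratio of FPKM plus 1, METTL3-OE over control (x axis), of each measured member (points) of the 25 ranked gene lists (rows, number of members in parentheses), with the list median (black bar) and the central 95% of medians of matched random lists (grey band). Red lists stood above the band, blue lists below it and grey lists within it; the estrogen-response median was highest at 0.98 and the embryo and yolk sac median lowest at -0.73 among members with FPKM of at least 1 (-0.12 with no filter, above that of trophoblast).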

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

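Leaving out genes with near-identical copies and the length and GC correction were chosen after the data were seen. No paired analysis was possible because each genotype has 1 library and the labels carry no replicate numbers. No replicate could be left out and no regrouping of samples could be made. The log2 ratio of Mettl3 stayed between 2.41 and 2.56 under the 4 alternatives run. The number of genes at least 2-fold higher or lower followed the pseudocount and the threshold. A pseudocount of 0.1 gave 331 higher and 220 lower, and a pseudocount of 0.5 gave 224 higher and, within 1.5 times the reported count, 175 lower. A 1.5-fold threshold gave 620 higher and 411 lower, and a 4-fold threshold 4 higher and 9 lower. The share of higher genes among those counted was 51.4%, and it was 43.5% with median-ratio scaling and 42.5% with the trimmed mean. In all, 15 of 22 gene counts stayed within 1.5 times. The factors of both scalings were 0.07 and 0.08 on the log2 scale. Of 223 list medians recomputed, 214 kept their side of the percentile limits. Ribosomal proteins, with the same median of 0.035, went from percentile 99.35 to 26.1 when the random lists were not matched on expression. Immediate early genes came inside the limits with a filter at FPKM 5 (median -0.13) and after the length and GC correction (-0.12). Uterine glands, with 7 members, passed the high limit without the most abundant genes (0.28 over 8 members), with no filter (0.20 over 11) and after the length and GC correction (0.50 over 6), and erythroid cells the low limit with no filter (-0.20) and with unmatched lists (-0.24). Progesterone receptor genes passed the low limit after the length and GC correction (-0.15). The embryo and yolk sac median was -0.12 with no filter, over 18 members in place of 6. The cause of these moves was not tested, except in the gland list. Without the most abundant genes, METTL3-OE values were divided by 0.981. Sox9, at 0.986 FPKM in METTL3-OE, then passed the filter as an added member. Kiss1 has no annotated length, and the 6 other gland genes had a median of 0.45 before the correction. For Pgr and the genes named by rank other than Mettl3, 96 log2 ratios were recomputed. Of these, 77 differed from the reported value by less than the counting error of a 2 kb transcript at the gene's FPKM. The genes' own lengths were not used, so this error is too wide for longer transcripts, such as Pgr, and too narrow for shorter ones. Pgr, at 0.02, had the opposite sign with median-ratio (-0.05) and trimmed-mean (-0.06) scaling, and no other had. Of the 259 genes at least 2-fold apart, 27 have a near-identical copy; without such genes 117 were higher and the counts stayed within 1.5 times. At these depths, 20 simulated pairs of equal libraries gave at most 1 gene at least 2-fold apart, so counting error is small beside the differences, while the spread between animals is unknown.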

Other observations

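The tests on the length and GC correction, on the estrogen-response genes and on Rps27 were chosen after the result was seen. The second decidual and second smooth muscle lists used below were not among the lists fixed before the data were examined. The kallikrein genes form a group outside the lists. Of 9 measured members on chromosome 7, 6 were at least 2-fold lower in METTL3-OE and 1 was at least 2-fold higher. Klk7, Klk8, Klk9, Klk10, Klk14 and Klk15 were the lower ones, with log2 ratios from -2.82 for Klk7 to -1.05 for Klk15. Klk1, the tissue kallikrein, was higher (26.5 against 9.18 FPKM, 1.43), a value that is uncertain because Klk1 has a near-identical copy, Klk1b5. Single abundant genes outside the lists were lower too. Psap, the precursor of the saposins, was at 2028 against 4910 FPKM (log2 ratio -1.28), Fabp4, a fatty acid-binding protein, at 175 against 446 FPKM (-1.34), Dbi, the acyl-CoA-binding protein, at 309 against 739 FPKM (-1.25), and Sphk1, sphingosine kinase, at 94.2 against 244 FPKM (-1.37). Of single genes that were higher, Dpt was at 41.9 against 13.3 FPKM (1.59), Ogn at 44.4 against 14.8 FPKM (1.52), Aspn at 8.40 against 2.66 FPKM (1.36) and Igfbp5 at 86.2 against 36.6 FPKM (1.22). These genes were chosen after their values were seen and stand for no tested group.

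Lower decidual genes together with higher muscle and matrix genes may reflect the make-up of the tissue as well as the state of the decidua. Natural killer (-0.26) and trophoblast (-0.42) medians were also lower in METTL3-OE, while epithelium (0.44) and macrophage (0.39) medians were higher. The labels do not give the number of implantation sites in each library, so their share of the tissue is unknown. Transcript length or GC bias as the whole cause is argued against by 3 of 3 lists outside the percentile limits after correction, although the matrix median went from 0.61 to 0.46. A second list of 15 smooth muscle genes had a median of 0.60 with 12 members above the median of all genes, as a larger share of myometrium predicted. Only 1 member lay below -0.2 (Rbpms2 at -0.24). Higher expression of such genes per cell would raise this list too, so it cannot tell a larger share from a changed state of the muscle. Whether a uniformly smaller share of decidua is the whole cause was not decided by a second decidual list of 8 measured genes. Its median was -0.06. In it 3 genes lay above 0.2, where a smaller share predicted none. They were Prl6a1 at 0.31, and Igfbp3 at 0.42 and Ptgis at 0.33, both also made outside the decidua. Another 3 lay below -0.2 (Ctla2b at -1.35, Dio3 at -0.30 and Bmp8a at -0.29), with Gpx3 at -0.13 and Ctla2a at 0.01 between them. Ctla2a and Ctla2b are uncertain as near-identical copies. Genes also made elsewhere can be higher with less decidua, so the list cannot exclude this cause. A smaller share of decidua, as the whole cause or part of it, stays open. So do, untested, a less mature decidua, an effect of METTL3 on decidual cells and ordinary variation between animals. An effect of Cre or of its insertion at Pgr, both absent from the control, cannot be told apart from one of METTL3.

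The higher estrogen-response genes could come from more epithelium, from a change within it, or from both. More epithelium as the whole cause stays open: the median of the estrogen list was 0.98 and that of the epithelium list 0.44, but single epithelial genes reached as high (Tacstd2 at 0.98), and a median set against single genes decides nothing. A higher transcript level of the estrogen receptor over the whole uterus is argued against by Esr1 at 0.014. A change of Esr1 within the epithelium alone could be hidden in this value and stays open. A larger share of one epithelial compartment, such as the lumen between implantation sites, and altered hormone levels or receptor activity remain open and were not tested.

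Rps27 and its copy Rps27rt differed in opposite directions, Rps27 with 1062 FPKM in METTL3-OE against 2866 in the control and Rps27rt with 2848 against 772 FPKM. Their transcripts align at 100% identity over 341 bases, and the summed FPKM was 3910 against 3638, a log2 ratio of 0.10. This is consistent with reads of one transcript being divided differently between identical copies in the 2 libraries. Rpl17, which was lower (221 against 671 FPKM), has 23 near-identical copies, and its value is uncertain in the same way, untested.

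METTL3 marks GGAC motifs and m6A can shorten the life of an RNA, so a hypothesis was that transcripts dense in GGACH (H being A, C or T) would be lower in METTL3-OE. Spearman's rho between motifs per kb of the longest transcript and the log2 ratio was -0.032 across 12295 genes, which are not independent replicates, and 0.031 after the length and GC correction. No such general trend was seen, and single methylated transcripts were not tested.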
